A study of Mus musculus with 4 samples.

How the data were processed

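Glomerular cells of WT and AS mice at 5 and 8 weeks were profiled in 4 libraries, 1 per genotype and age, with Chromium single-cell 3' chemistry, kit version 2 per the labels. The deposited values are raw UMI counts per gene and barcode, made with Cell Ranger 9.0.0 per the file headers. The submitters' processing notes name bcl2fastq 2.20.0, STAR 2.7.2a and the mouse genome GRCm38 (mm10). The matrices hold called barcodes only, each with at least 500 UMIs, and further filters are not stated. The files list 55488 genes, of which 55141 IDs are found among the 55450 of GENCODE M21. For 114 symbols more than 1 gene ID exists, and 2 list members with such a symbol were left out.

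Cells with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs were kept. At 5 weeks 840 WT and 751 AS barcodes failed the minimum, and 7 and 29 more the mitochondrial maximum. At 8 weeks 1074 WT and 657 AS barcodes failed the minimum, and 129 and 13 more the maximum. Scrublet, run per library with an expected doublet rate of 6%, called 3.32% of WT and 4.67% of AS cells at 5 weeks and 2.86% and 6.58% at 8 weeks, and these were left out. Its score threshold, set per library, was 0.237 in WT and 0.195 in AS at 5 weeks, and 0.2504 and 0.1478 at 8 weeks. Doublets were therefore not removed at the same score in WT and AS. The median kept cell had 3573 and 3474 genes at 5 weeks and 3822.5 and 4006 at 8 weeks (WT, then AS).

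The kept cells of all libraries were clustered together without batch integration, with counts scaled to 10000 per cell and log-transformed, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1, which gave 27 clusters. Clusters were named from markers fixed before the data were seen. A name needed 3 detected markers, a lead of 1 log2 over the next class, and leading genes that do not go against it. The lead of 1 log2, the purity of 80% and the rule that a cluster with a depth under 1/3 of its library's stays unnamed were set after the clusters were seen. Low depth kept out 7.53% of WT and 5.97% of AS cells at 5 weeks and 15.7% and 5.87% at 8 weeks. Classes that scored alike kept out 2.03% and 3.01% at 5 weeks and 5.11% and 1.84% at 8 weeks. Low purity kept out 2.71% and 0.016% at 5 weeks and 0% and 0.059% at 8 weeks, in a single interferon-rich cluster of 156 cells. Leading genes against the name kept out 2.19% and 2.06% at 5 weeks and 5.63% and 1.92% at 8 weeks, and a cell state rather than a class 1.42% and 0.016% at 5 weeks and 0.098% and 0.499% at 8 weeks.

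Counts were summed per class and library and given as CPM of the class total. Podocyte-like totals were 25823930 and 32937472 UMIs at 5 weeks and 39803949 and 61878913 at 8 weeks (WT, then AS). Glomerular endothelial-like totals were 17433978, 23008281, 5708657 and 18315612 UMIs in the same order, and mesangial-like totals 13882346, 18815980, 2116878 and 20877293. The comparison of AS with WT at each age was log2((CPM in AS + 5)/(CPM in WT + 5)). With 1 library per group no test was run. Intervals are exact Poisson for levels, exact conditional binomial for ratios and Clopper-Pearson for shares, at 95%, and cover counting error only. The pseudocount enters both ends of a ratio's interval, so where a library holds few UMIs of a gene it keeps the interval narrow.

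Genes were named by a rule fixed beforehand. Within a class and age, genes with at least 30 UMIs and 20 CPM in 1 of the 2 libraries were ranked by log2 ratio, and the 8 highest and 8 lowest in podocyte-like cells and 5 and 5 in the other classes were named. The same numbers were named among genes with the same sign at both ages, ranked by the smaller ratio. Mitochondrial, ribosomal protein, hemoglobin, sex-specific and unnamed genes were left out, as were genes at a free RNA level, under 10% of the level of another class with at least 50 cells in both libraries. Tnfsf15, Tnfrsf25, Col4a3, Col4a4 and Col4a5 were given in every main class, and of each list 2 to 4 members with the largest ratio. Some genes that this rule names are not reported here.

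The 19 gene lists fixed beforehand were basement membrane, slit diaphragm and podocyte identity, podocyte injury, TNF superfamily, NF-kB and inflammatory response, TGF-beta response and interstitial matrix, interferon response, antigen presentation, p53 targets, unfolded protein response, immediate-early and dissociation response, endothelial signalling, actin cytoskeleton, cholesterol synthesis, oxidative phosphorylation, complement, circadian clock, glucocorticoid response, and a sex check. A list's median log2 ratio over at least 5 members past the floor was placed among the medians of 10000 random lists of the same size matched on expression in 20 bins. Such a percentile only describes the libraries compared, as lists also lay far out between the WT libraries. A member counted as higher or lower at 1.5-fold. Ratios at the 2 ages were correlated across genes. For shares of cells with a Tnfsf15 UMI and for sums of genes per cell, cells were thinned to 5000 UMIs without replacement and shallower cells left out.

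The method was tested on counts simulated with Poisson noise from the pooled podocyte-like profile of both WT libraries. In the simulated 5-week pair 6717 genes passed the floor. Such counts hold no difference between animals or preparations, so the test covers counting error only. Genes simulated 2-fold higher had a median log2 ratio of 0.93 and held 100% of the 100 highest ranks, and genes simulated 2-fold lower had a median of -0.89. Of 200 unchanged lists 2.5% fell outside the central 95%, and simulated ratios with no shared change correlated at r 0.0103.

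The 11 alternatives fixed beforehand were median-of-ratios scaling, a pseudocount of 1 CPM, the mean of each cell's CPM, cells with a low immediate-early share, no expression floor, a mitochondrial maximum of 10%, a minimum of 1000 genes and 2000 UMIs, doublets kept, Leiden resolutions 0.5 and 2, and thinned shares. After the results were seen, 3 more were added: the WT library of the other age, low-depth clusters named, and genes at a free RNA level left out. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.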

Results

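Single-cell RNA sequencing was carried out on glomeruli, the filtering units of the kidney, from wild-type mice (WT) and from mice with a premature stop in the X-linked gene Col4a5 (AS), a model of Alport syndrome. Alport syndrome is an inherited kidney disease in which chains of type IV collagen are missing from the glomerular basement membrane. Mice were 5 weeks old, described by the submitters as before the onset of disease, or 8 weeks old, when protein leaks mildly into the urine and the membrane and podocytes look abnormal. The tissue field of the labels names embryonic kidney, whereas the titles and the study design give 5 and 8 weeks, and the ages of the titles are used here. Each of the 4 groups had 1 library, so no difference has a replicate check, no p-value is given, and each comparison is between 2 libraries. Intervals are 95% intervals that cover counting error only.

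The 5-week libraries held 74356581 UMIs (unique molecular identifiers, counted mRNA molecules) in 6604 barcodes for WT and 96045236 UMIs in 7544 barcodes for AS. The 8-week libraries held 79595446 UMIs in 7489 barcodes for WT and 126118422 UMIs in 7963 barcodes for AS. After filtering and removal of called doublets, 5566 WT and 6448 AS cells remained at 5 weeks, and 6106 WT and 6813 AS cells at 8 weeks. The median kept cell had 9402 UMIs in WT and 8525 in AS at 5 weeks, and 10296.5 in WT and 10915 in AS at 8 weeks.

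Podocyte-like, glomerular endothelial-like and mesangial-like cells were the 3 classes compared between genotypes. Podocytes are the epithelial cells that wrap the capillaries, and mesangial cells are the pericyte-like cells between them. Podocyte-like cells made up 27.7% (interval 26.6 to 28.9) of WT and 23.2% (22.1 to 24.2) of AS cells at 5 weeks, and 44.6% (43.3 to 45.8) and 35.2% (34.0 to 36.3) at 8 weeks. Glomerular endothelial-like cells made up 39.3% of WT and 46.2% of AS cells at 5 weeks, and 14.99% and 32.5% at 8 weeks. Mesangial-like cells made up 11.7% and 14.0% at 5 weeks, and 2.64% (2.25 to 3.07) and 18.0% (17.1 to 19.0) at 8 weeks. The WT 8-week library also held more cells from outside the glomerular tuft: renin cell-like cells made up 6.19% there and 0.977% to 1.28% in the other libraries, and distal tubule-like cells made up 1.38% there and 0.132% or less in the others. Clusters that stayed unnamed held 15.9% of WT and 11.1% of AS cells at 5 weeks and 26.6% and 10.2% at 8 weeks. At clustering resolution 2 glomerular endothelial-like shares were 6.22% in WT and 29.9% in AS at 8 weeks, and renin cell-like cells made up 1.16% of the WT 8-week library and 0.323% to 0.377% of the others. With doublets kept, renin cell-like cells made up 4.33% of the WT 8-week library and 2.26% of the AS 5-week library, and at resolution 0.5 the mesangial-like share of the WT 8-week library was 4.18%. The isolation of glomeruli can set all of these shares.

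The remaining named classes were small. Arterial endothelial-like cells made up 2.03% of WT and 1.99% of AS cells at 5 weeks and 2.82% and 1.34% at 8 weeks. B-like cells made up 1.28% and 1.504% at 5 weeks and 0.393% and 0.778% at 8 weeks. T and NK-like cells made up 0.898% and 0.977% at 5 weeks and 0.18% and 0.572% at 8 weeks. Fibroblast-like cells numbered 22 in all. Parietal epithelial cells formed no named cluster, so no comparison was made for them.

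Different clusters held the podocyte-like cells of each library. Cluster 0 held 1294 of the 1544 WT cells at 5 weeks, and clusters 1 and 20 held 754 and 453 of the 1494 AS cells. Cluster 2 held 2391 of the 2722 WT cells at 8 weeks, and clusters 20 and 22 held 1158 and 935 of the 2396 AS cells. Glomerular endothelial-like cells lay in clusters 3, 4, 10 and 18, of which cluster 4 held 1282 of 2190 WT and 1519 of 2982 AS cells at 5 weeks. At 8 weeks cluster 3 held the largest number of cells of both genotypes, 475 of 915 in WT and 773 of 2213 in AS, and cluster 18 held 488 AS and 31 WT cells. Mesangial-like cells were a single cluster, number 9, with 653 WT and 903 AS cells at 5 weeks and 161 and 1228 at 8 weeks.

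Col4a5, the mutated gene, encodes the α5 chain of type IV collagen, which assembles with the chains of Col4a3 and Col4a4. In podocyte-like cells its level was lower in AS at both ages. At 5 weeks it was 549 CPM (UMIs scaled to the class total; interval 539.8 to 558) in WT and 193 CPM (189 to 198) in AS, a log2 ratio of -1.48 (-1.52 to -1.44). At 8 weeks it was 387 CPM (381 to 393) in WT and 203 CPM (199 to 206) in AS, a log2 ratio of -0.92 (-0.95 to -0.88). These ratios were -0.98 and -1.41 with the WT library of the other age. A 3' tag outside a point mutation checks the genotype labels only as far as the transcript is lost. Col4a3 and Col4a4 were slightly higher in AS podocyte-like cells, with log2 ratios of 0.15 and 0.21 at 5 weeks and 0.26 and 0.25 at 8 weeks. The WT library of the other age put them at 0.35 and 0.65 at 5 weeks and at 0.05 and -0.20 at 8 weeks, so for Col4a4 the 8-week direction turned. Col4a6, the neighbour of Col4a5 that encodes the α6 chain, stood at 27.6 CPM in WT and 61.5 CPM in AS at 5 weeks and at 33.6 and 75.8 CPM at 8 weeks, log2 ratios of 1.03 and 1.07. Glomerular endothelial-like cells had Col4a3 log2 ratios of -0.11 at 5 weeks and -1.28 at 8 weeks, Col4a4 of -0.05 and -1.32, and Col4a5 of -0.34 and -1.73. In mesangial-like cells Col4a3 had log2 ratios of -0.57 and -1.65, Col4a4 of -0.42 and -1.84, and Col4a5 of -0.87 and -1.99. Against the WT library of the other age Col4a3, Col4a4 and Col4a5 were at -1.16, -1.08 and -1.76 at 5 weeks and -0.23, -0.29 and -0.31 at 8 weeks in glomerular endothelial-like cells. In mesangial-like cells they were then at -1.97, -1.63 and -2.31 at 5 weeks and -0.25, -0.63 and -0.54 at 8 weeks. With doublets kept the 8-week mesangial-like ratios of Col4a3 and Col4a5 were -0.9955 and -1.004, and with a pseudocount of 1 CPM those of Col4a5 were -1.85 and -2.91. The levels of all 3 genes in these classes were below 10% of the podocyte-like level.

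On GRCm38 with GENCODE M21, Col4a5 (ENSMUSG00000031274) lies on chromosome X from 141475385 to 141689234 on the plus strand. Col4a3 (ENSMUSG00000079465) lies on chromosome 1 from 82586921 to 82722059 on the plus strand and Col4a4 (ENSMUSG00000067158) on chromosome 1 from 82448423 to 82586849 on the minus strand. Tnfsf15 (ENSMUSG00000050395) lies on chromosome 4 from 63727084 to 63745113 on the minus strand, and Tnfrsf25 (ENSMUSG00000024793) on chromosome 4 from 152115934 to 152120119 on the plus strand. These spans are whole genes with exons and introns.

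Tnfsf15 encodes TL1A, a cytokine of the TNF superfamily, and was singled out by the study on these same samples, so its direction here is not independent evidence. In podocyte-like cells it was higher in AS than in WT before disease onset, and the ratio was larger at 8 weeks. At 5 weeks it stood at 30.6 CPM (28.5 to 32.8) in WT and 92.0 CPM (88.8 to 95.4) in AS, a log2 ratio of 1.45 (1.35 to 1.55). At 8 weeks it stood at 36.9 CPM (35.0 to 38.8) in WT and 199 CPM (195 to 202) in AS, a log2 ratio of 2.28 (2.21 to 2.35). Between the WT libraries the log2 ratio of 8 over 5 weeks was 0.23 (0.12 to 0.34). Tnfsf15 in glomerular endothelial-like cells was at 0.287 CPM in WT and 0.869 CPM in AS at 5 weeks and at 1.23 and 3.17 CPM at 8 weeks. In mesangial-like cells it was at 0.360 and 0.213 CPM at 5 weeks and at 3.31 and 1.82 CPM at 8 weeks. The 39 T and NK-like cells of the AS 8-week library held 25 Tnfsf15 UMIs, or 62.4 CPM (40.4 to 92.1).

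The share of podocyte-like cells with a Tnfsf15 UMI was also higher in AS. It was 30.2% (27.9 to 32.5) in WT and 67.3% (64.8 to 69.6) in AS at 5 weeks, and 33.1% (31.3 to 34.9) and 82.5% (80.9 to 84.0) at 8 weeks. With each cell thinned to 5000 UMIs it was 12.9% in WT and 33.3% in AS at 5 weeks, and 15.3% and 54.0% at 8 weeks. Thinning left out 95 WT and 67 AS cells at 5 weeks, and 260 and 204 at 8 weeks. TL1A is known as a product of endothelial cells, and in glomerular endothelial-like cells the thinned shares were 0.232% and 0.605% at 5 weeks and 0.876% and 1.22% at 8 weeks, with 467, 834, 344 and 736 cells left out in the same order. The unthinned shares there were 0.228%, 0.637%, 0.765% and 2.26%. In mesangial-like cells the thinned shares were 0.159%, 0.231%, 2.22% and 1.17% with 23, 37, 26 and 118 cells left out, and the unthinned shares 0.766%, 0.443%, 3.73% and 2.85%. Median depth was 16246 and 17810.5 UMIs in WT and AS podocyte-like cells at 5 weeks and 14396.5 and 20248 at 8 weeks, against 6969.5, 6238.5, 5753 and 6339 in glomerular endothelial-like cells and 14663, 15154, 8490 and 12662.5 in mesangial-like cells. The receptor gene Tnfrsf25 was low in podocyte-like cells, with 3.37 CPM in WT and 3.67 CPM in AS at 5 weeks and 2.61 and 3.13 CPM at 8 weeks, log2 ratios of 0.05 (-0.12 to 0.22) and 0.10 (-0.03 to 0.22). It was at 0.764 CPM or less in glomerular endothelial-like cells and at 2.36 CPM or less in mesangial-like cells of every library.

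**Figure D1:**
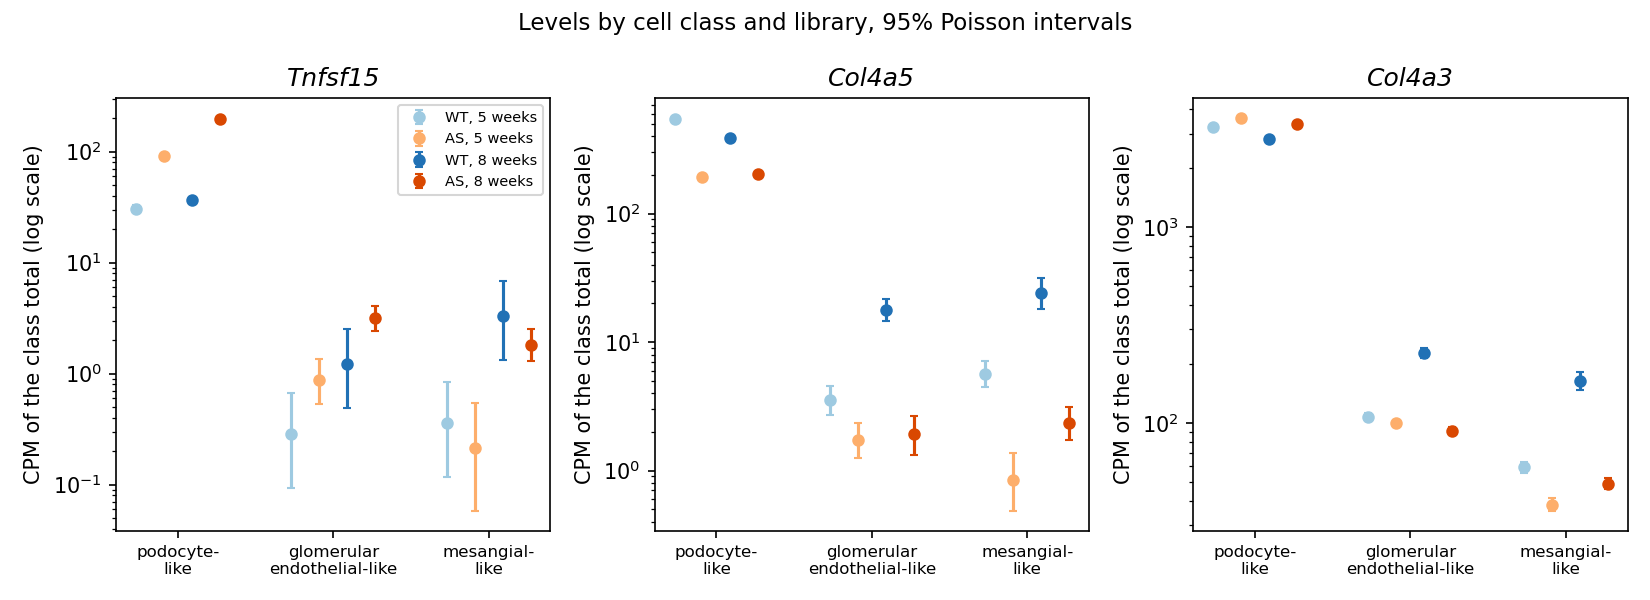
Levels of Tnfsf15, Col4a5 and Col4a3 in CPM of the class total (log axis) for the 3 main cell classes, with 1 point per library and bars for the 95% Poisson interval. In podocyte-like cells Tnfsf15 is higher and Col4a5 lower in AS than in WT at both ages, while in the other classes Tnfsf15 stays at or below 3.31 CPM.

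The 5-week comparison asks what differs in AS podocytes before disease onset. Among the genes with the highest ratios were Rbfox1, a splicing regulator, at 42.8 CPM in WT and 288 CPM in AS (log2 ratio 2.62), and Igfbp2, which binds insulin-like growth factors. Igfbp2 had 2 UMIs in WT and 734 in AS, a log2 ratio of 2.43 (2.36 to 2.45) with the pseudocount of 5 CPM and of 4.43 with 1 CPM. The pseudocount kept that interval narrow. The metallothioneins Mt1 and Mt2 had log2 ratios of 2.49 and 2.01, the stress-inducible Gadd45b 2.2, the immediate-early transcription factor Egr1 2.22, and the actin-binding Cald1 2.07, from 186 CPM in WT to 799.9 CPM in AS. Rims2, known from presynaptic terminals, had a log2 ratio of 2.03. The lowest ratios were those of B2m, the light chain of MHC class I, at 482 CPM in WT and 98.4 CPM in AS (log2 ratio -2.24), and of the interferon-inducible GTPases Irgm1 (-1.67) and Irgm2 (-1.50). Mgat5b, a glycosyltransferase (-1.60), Opcml, a cell adhesion molecule (-1.47), Nrep (-1.46) and the calcium channel subunit Cacna2d2 (-1.45) were also low, beside Col4a5 itself. B2m turned to 0.18 when the WT library of the other age was used, and Irgm1 was at -0.09, Irgm2 at -0.03, Nrep at -0.26, Cacna2d2 at -0.92, Opcml at -3.34, Mt1 at 0.30, Mt2 at 0.35, Rbfox1 at 1.59, Cald1 at 1.19 and Rims2 at 1.19. Of 55 named genes and leading list members past 1.5-fold in this class at 5 weeks 39 stayed past it with that library, and of 64 at 8 weeks 54. The named podocyte-like log2 ratios had counting interval arms with a median of 0.085 and a largest of 0.145.

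By gene list, injury-associated genes were already higher in AS podocyte-like cells at 5 weeks. The podocyte injury list had a median log2 ratio of 0.49, at percentile 99.98 of 10000 random lists matched on expression, and 3 of its 7 measured members were at least 1.5-fold higher. Its largest ratios were those of S100a6 (2.55), Ccn2 (1.41) and Ccn1 (1.09), the last 2 being matricellular proteins. Fewer than 5 members of this list passed the floor in the WT libraries. Some were thus measured only because of their level in AS, which favours higher members. Of the 6 measured TNF superfamily genes, Tnfsf15 and the receptor Tnfrsf12a (0.93) were at least 1.5-fold higher, with a list median of 0.32 at percentile 99.8. The study chose Tnfsf15 on these samples, so this count is not independent of that choice. The NF-kB and inflammatory list had a median of 0.35 at percentile 99.5, with 2 of 5 members higher, Nfkbia at 1.06 and Relb at 0.86, and 1 lower. The immediate-early list had a median of 0.23 at percentile 98.2, with 3 of 9 members higher, among them Egr1 at 2.22 and Junb at 1.24. In the WT libraries 7 members of that list passed the floor, so some of the 9 were measured only because of their level in AS. The oxidative phosphorylation list had a median of 0.23 at percentile 99.9, with 1 of 21 members past 1.5-fold. With no expression floor the medians were 0.23 for the injury list, 0.02 for TNF superfamily genes and 0.03 for NF-kB. In cells with a low immediate-early share the immediate-early median was -0.0092, with Egr1 at 0.9992 and Junb at 0.77. The TNF superfamily median was 0.06, the immediate-early median 0.03 and the injury median 0.77 with the WT library of the other age.

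Interferon and antigen presentation genes were lower in AS podocyte-like cells at 5 weeks. Of the interferon list 6 of 7 measured members were at least 1.5-fold lower, with a median of -0.86 below all 10000 random lists, and Gbp2 (-1.42) and Igtp (-1.16) were among them. Of the antigen presentation list 4 of 7 were lower, with a median of -0.89, again below all random lists. The WT 5-week library was also above the WT 8-week library for the interferon list, with a median log2 ratio of 8 over 5 weeks of -1.14 in this class. Circadian clock genes had a median of -0.35 at percentile 0.01 with no member past 1.5-fold, Tef at -0.42 and Cry2 at -0.39. The slit diaphragm and podocyte identity list had a median of -0.11 at percentile 0.28, with 1 of 30 members lower, Thsd7a at -0.69, and 1 higher, the cell cycle inhibitor Cdkn1c at 0.80. The basement membrane list had a median of -0.03 at percentile 37.7 over 13 members. Medians and percentiles of the remaining lists were 0.06 and 67.4 for TGF-beta and interstitial matrix, 0.10 and 90.5 for actin cytoskeleton, -0.11 and 5.98 for the unfolded protein response, -0.29 and 0.51 for endothelial signalling, -0.05 and 35.4 for cholesterol synthesis, and 0.00 and 45.7 for p53 targets. With no expression floor the interferon median was -0.51 and the antigen presentation median -0.4976, and with the WT library of the other age the antigen presentation median turned to 0.18 and the circadian median was -0.72. That library also turned Gbp2 to 0.63 and Igtp to 0.0376, whereas with doublets kept they were at -3.28 and -2.25. With doublets kept the endothelial signalling median turned to 0.45. The immediate-early list made up 1298 CPM of WT and 1489.9 CPM of AS podocyte-like counts.

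The 8-week comparison asks what differs once proteinuria is mild. With the pseudocount of 5 CPM the highest ratio in podocyte-like cells was that of Epha6, an ephrin receptor, at 6.004 CPM in WT and 367 CPM in AS, a log2 ratio of 5.08 (4.98 to 5.18). Igfbp2 had 1 UMI in WT and 7092 in AS, a log2 ratio of 4.57 (4.54 to 4.58), with an interval kept narrow by the pseudocount. The Igfbp2 ratio was 2.48 in cells with a low immediate-early share. S100a6, a calcium-binding protein (4.50), the actin-binding Tagln (4.49, from 22.9 CPM in WT to 622 CPM in AS), the chemokine Cxcl10 (3.58), the calcineurin regulator Rcan2 (3.56), Xkr4 (3.34) and Gadd45b (3.08) followed. The lowest with this pseudocount was Opcml, at 532 CPM in WT and 18.4 CPM in AS, a log2 ratio of -4.52 (-4.59 to -4.45). Astn2 (-2.00), Mgat5b (-1.88), the connexin gene Gja3 (-1.74), the atypical chemokine receptor Ackr3 (-1.59) and the glucocorticoid-induced Fkbp5 (-2.15) were also low. Kap and S100g, tubule genes, had ratios of -3.49 and -2.84, with 52.2 and 31.8 CPM in the WT 8-week library and 0.129 CPM or less in each of the other libraries. With a pseudocount of 1 CPM the order was another, with Igfbp2 at 6.82, Epha6 at 5.72, Cxcl10 at 5.42, Kap at -5.60, S100g at -4.86 and Opcml at -4.78. Kap, S100g and Fkbp5 were at 0.0277, 0.0257 and 0.0032, and Opcml at -2.65, with the WT library of the other age.

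Injury, stress, cytoskeletal and inflammatory lists were higher in AS podocyte-like cells at 8 weeks. Of the podocyte injury list 8 of 9 measured members were at least 1.5-fold higher, with a median log2 ratio of 1.99 above all 10000 random lists. S100a6 was at 4.50, Ccn1 at 2.95 and Ccn2 at 2.92. Fewer than 5 members of the injury list passed the floor in the WT libraries. Some were thus measured only because of their level in AS, which favours higher members in this count. Of the actin cytoskeleton list 10 of 20 members were higher and 1 lower, with a median of 0.55, and Tagln, Tpm1 (1.41) and Cnn2 (1.39) led it. Of the unfolded protein response list 6 of 14 were higher, with a median of 0.55, among them Manf (1.37), the chaperone Hspa5 (1.26), Creld2 (1.23) and Dnajb9 (1.0). Of the TGF-beta and interstitial matrix list 6 of 11 were higher and 1 lower, with a median of 0.62, and besides Ccn2 these included Tgfb2 (1.82) and Bgn (1.75), whose levels were under 10% of another class's. Of the NF-kB list 5 of 7 were higher, with a median of 0.89, Cxcl10 leading it, with Nfkbia at 1.38 and Relb at 1.26. The antigen presentation list had a median of 0.84, with 4 of 6 higher, H2-K1 at 1.22 and B2m at 1.07. The immediate-early list had a median of 0.71 with 7 of 11 higher, Egr1 at 2.71 and Junb at 1.79. In the WT libraries 5 members of the NF-kB list, 8 of the TGF-beta list, 7 of the immediate-early list and 19 of the actin list passed the floor. Their counts of higher members thus also include members measured only because of their level in AS. These lists, from actin to immediate-early, lay above all random lists, and the interferon list lay at percentile 99.9 with a median of 0.63 and 4 of 7 members higher, Gbp2 at 1.33. Between the 2 WT libraries, without the mutation, most of these lists lay far out too. Their percentiles for 8 over 5 weeks were 0.39 for actin, 0.16 for the unfolded protein response, 0.71 for TGF-beta, 0.0 for antigen presentation and 99.965 for immediate-early. NF-kB lay at 43.7. The percentiles above therefore do not by themselves point to genotype. With no expression floor the 8-week medians of AS to WT were 1.232 for injury, 0.1972 for NF-kB, 0.17 for TGF-beta, 0.32 for interferon, 0.36 for antigen presentation and 0.25 for immediate-early. In cells with a low immediate-early share they were 1.23 for injury, 0.24 for TGF-beta and 0.29 for immediate-early, with Egr1 at 1.1976 and Junb at 0.98, and the injury member at the median was at a free RNA level. With the WT library of the other age the interferon and antigen presentation medians turned to -0.72 and -0.21, and the TGF-beta and immediate-early medians were 0.36 and 1.08, with B2m at -1.35 and Gbp2 at -0.72.

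The podocyte identity list had a smaller median in absolute size than the lists above. The difference between lists was not tested, and the NF-kB and TGF-beta medians shrank with no expression floor. The slit diaphragm and podocyte identity list had a median of -0.14 at percentile 3.21, with Thsd7a at -1.02 and the transcription factors Lmx1b at -0.66 (-0.53 in cells with a low immediate-early share) and Wt1 at -0.56, and 2 of 30 members were at least 1.5-fold lower. The basement membrane list had a median of 0.00 at percentile 51.5, with 4 of 13 members higher, among them Col4a6, Sparc (0.93) and Npnt (0.74). The TNF superfamily list had a median of 0.15 at percentile 88.5, with 2 of 6 higher, Tnfrsf12a at 2.39 and Tnfsf15, again not independent of the study's choice. The circadian clock list had a median of -0.47 at percentile 0.01, with Tef at -0.67 and Per1 at -0.58, and the glucocorticoid response list of -0.58 at percentile 0.03, with Mt1 at 1.74 and Mt2 at 1.55 in the other direction. With doublets kept the glucocorticoid median turned to 0.16, and with the WT library of the other age the circadian median was -0.21. Between the WT libraries, the glucocorticoid list had a median log2 ratio of 8 over 5 weeks of 1.66 and the circadian list of 0.40. Medians and percentiles were 0.15 and 90.9 for oxidative phosphorylation, -0.24 and 12.4 for endothelial signalling, 0.00 and 70.0 for cholesterol synthesis, and -0.01 and 59.4 for p53 targets. With median-of-ratios scaling the median gene's 8-week log2 ratio in podocyte-like cells was 0.105 higher, which applies to all values of this comparison and turns the p53 median to 0.10.

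**Figure D2:**
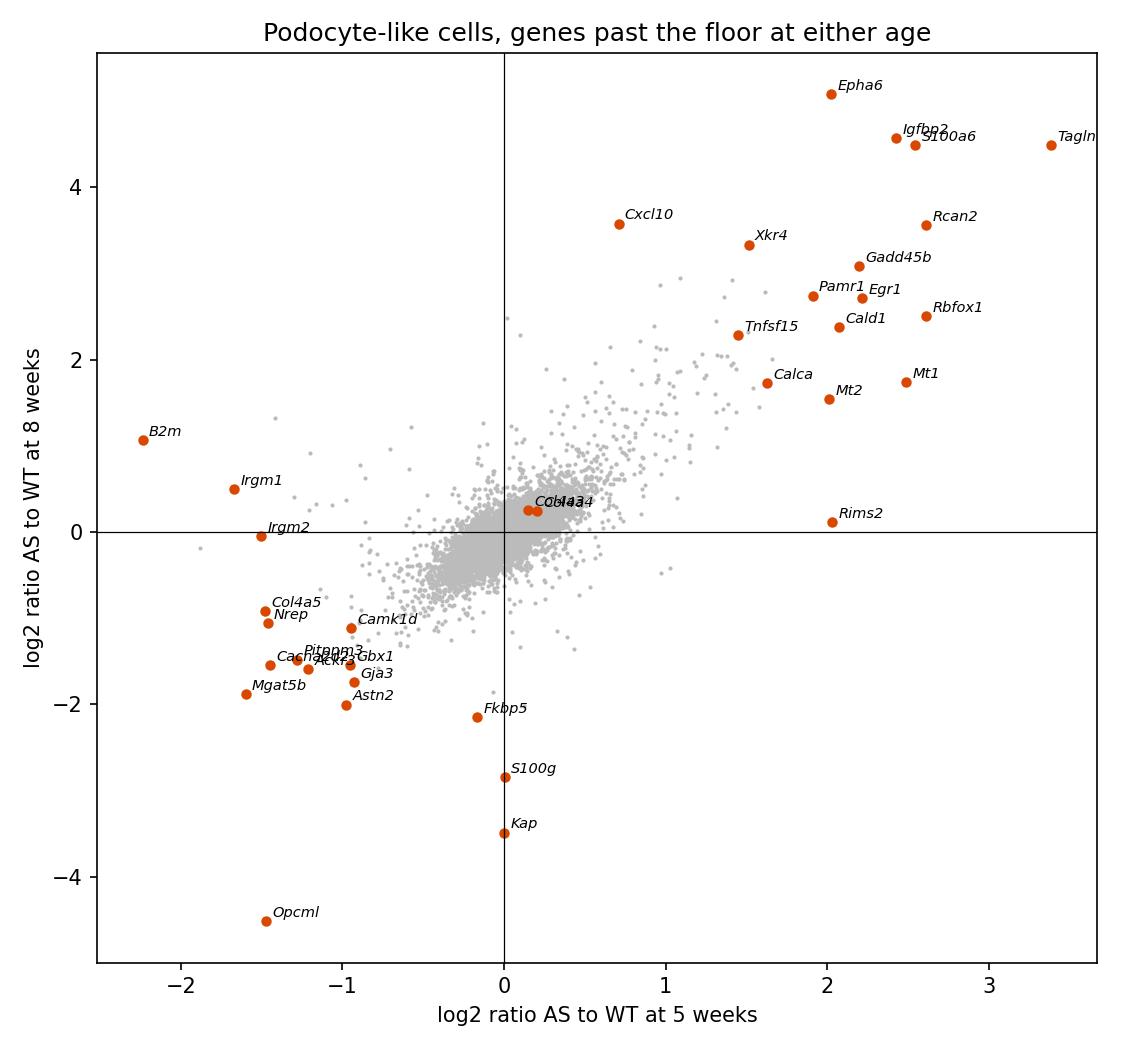
Log2 ratios of AS to WT in podocyte-like cells at 5 weeks (horizontal) and 8 weeks (vertical), with 1 grey point per gene past the expression floor at either age and named genes in orange. The named genes include 16 chosen for having the same sign at both ages, and B2m (-2.24 and 1.07) lies in opposite directions.

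The ratios at the 2 ages come from separate pairs of libraries and were compared across genes, which are not independent replicates. In podocyte-like cells they correlated with Pearson r 0.781 and Spearman rho 0.748 over 6675 genes, and 78.7% of genes had the same sign. In glomerular endothelial-like cells r was 0.319 and rho 0.335 over 7167 genes, with 62.0% of the same sign, and r was 0.167 in cells with a low immediate-early share. In mesangial-like cells r was 0.2002 and rho 0.187 over 7196 genes, with 55.9%. With the WT library of the other age r was 0.438 in podocyte-like, -0.259 in glomerular endothelial-like and -0.263 in mesangial-like cells. The standard deviation of the podocyte-like ratios was 0.28 at 5 weeks and 0.39 at 8 weeks, against 0.23 between the WT libraries of the 2 ages. For glomerular endothelial-like cells these were 0.18, 0.25 and 0.27, and in mesangial-like cells 0.20, 0.27 and 0.30. Outside podocyte-like cells the spread between genotypes was thus no larger than that between the WT libraries. The spread includes counting error, and the WT 8-week library was the shallowest in these classes, with 5708657 and 2116878 UMIs. These values therefore do not show that the genotypes differ little there.

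Among genes above a free RNA level, those highest in podocyte-like cells at both ages were Rbfox1 (2.62 at 5 weeks and 2.51 at 8 weeks), Igfbp2, Egr1 (2.22 and 2.71) and Gadd45b (2.2 and 3.08). Cald1 (2.07 and 2.38), Pamr1 (1.91 and 2.75), Mt1 (2.49 and 1.74) and Calca (1.63 and 1.73), which encodes calcitonin and calcitonin gene-related peptide, followed. Tagln (3.39 and 4.49), Rcan2 (2.61 and 3.56) and S100a6 (2.55 and 4.50) would have ranked above these by the smaller ratio. The free RNA rule left them out of this ranking. The podocyte-like genes lowest at both ages were Mgat5b (-1.60 and -1.88), Opcml (-1.47 and -4.52), Pitpnm3 (-1.28 and -1.48), Ackr3 (-1.21 and -1.59), Nrep (-1.46 and -1.06), Astn2 (-0.98 and -2.00), the homeobox gene Gbx1 (-0.95 and -1.54) and the kinase gene Camk1d (-0.95 and -1.11). Camk1d also stood at 905 CPM in the WT 5-week and 128 CPM in the WT 8-week library, a log2 ratio of -2.78, and with the WT library of the other age its 5-week log2 ratio turned to 1.83. That alternative also put Mt1 at 0.30 and 3.93 and Nrep at -0.26 and -2.26.

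The 50 genes with the highest 8-week ratios, Tnfsf15 left out, were summed per podocyte-like cell after thinning to 5000 UMIs. The median cell held 6 UMIs of these genes in WT and 36 in AS at 8 weeks, the age at which they were chosen. At 5 weeks, in libraries not used to choose them, the median cell held 5 in WT and 16 in AS. The lower and upper quartiles at 5 weeks were 3 and 8 in WT and 11 and 23 in AS.

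**Figure D3:**
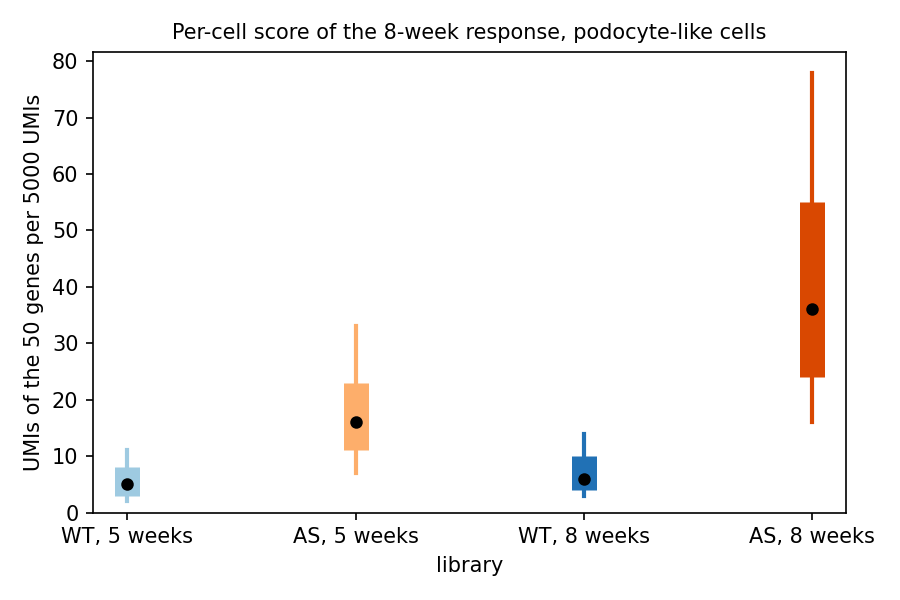
UMIs of the 50 genes with the highest 8-week ratios per podocyte-like cell thinned to 5000 UMIs, by library; points are medians, wide bars quartiles and thin bars the span from the 10th to the 90th percentile. The AS 5-week cells, with a median of 16, lie between the WT cells (5 and 6) and the AS 8-week cells (36).

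Among the genes higher at both ages in glomerular endothelial-like cells was Ednrb, the endothelin receptor type B, at 155 CPM in WT and 555 CPM in AS at 5 weeks and at 229 and 846 CPM at 8 weeks, log2 ratios of 1.81 (1.75 to 1.86) and 1.86 (1.78 to 1.94). The adhesion molecule gene Sdk1 (1.91 and 1.45), Cdk5rap1 (1.13 and 1.15), Tmem181b-ps (1.21 and 0.87) and the potassium channel gene Kcnh1 (0.87 and 1.73) were also higher at both ages. Lower at both ages were the desaturase gene Scd2 (-0.89 and -0.80), Sparcl1 (-0.74 and -1.79), F8, which encodes coagulation factor VIII (-0.66 and -0.70), Coil (-0.63 and -1.21) and the connexin gene Gja5 (-0.57 and -1.44). At 5 weeks Eps8l1 had a log2 ratio of 1.22, and Slc15a2 (-1.30), Nlrc5, a transactivator of MHC class I (-1.27), B2m (-1.14), Tgtp2 (-1.10) and Olfml2b (-1.08) were lowest. At 8 weeks Slc15a2, a peptide transporter, had 2 UMIs in WT and 563 in AS (2.74, interval 2.5 to 2.83, and 4.55 with a pseudocount of 1 CPM), followed by Creb5 (1.94) and the protease gene Adamts9 (1.89). The lowest at 8 weeks were the tubule genes Kap (-4.50), S100g (-3.84), Klk1 (-3.56) and Fxyd2 (-2.78), and Esr2 (-2.04). At resolution 2 the 8-week ratios of Sdk1, Kcnh1 and Esr2 were 0.84, 1.05 and -1.34, and the 5-week ratio of Gja5 was -0.04. Against the WT library of the other age Slc15a2 turned to 1.54 at 5 weeks and -0.11 at 8 weeks and Olfml2b to 0.56 at 5 weeks, where Nlrc5 was at -0.33, B2m at -0.25, Tgtp2 at -0.56 and Sdk1 at 0.82. At 8 weeks it put Kap at 0.13, S100g at 0.0258, Klk1 at 0.0574, Fxyd2 at 0.10, Esr2 at -0.04, Creb5 at 1.17 and Sdk1 at 2.53. Of 26 named genes and leading list members past 1.5-fold at 5 weeks 13 stayed past it with that library, and of 54 at 8 weeks 24. At resolution 2, 41 of those 54 did. The named ratios in this class had counting interval arms with a median of 0.152 and a largest of 0.29.

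Ednrb and Sdk1 were also among the 10 leading genes of cluster 18. That cluster held 31 of the 915 WT and 488 of the 2213 AS glomerular endothelial-like cells at 8 weeks. The class ratios could therefore depend on the make-up of the class. Ratios within clusters were computed after the class values were seen. At 8 weeks Ednrb had log2 ratios of 2.28 in cluster 3, 1.29 in cluster 4, 1.57 in cluster 10 and 0.34 (0.13 to 0.56) in cluster 18. Sdk1 had 1.96, 1.48 and 1.13 in the first 3 of these, and -1.37 (-1.64 to -1.10) in cluster 18. At 5 weeks the ratios of Ednrb ran from 0.86 in cluster 18 to 2.15 in cluster 10, and those of Sdk1 from 1.19 in cluster 18 to 2.27 in cluster 4. Ednrb was thus higher in AS in each of these clusters at both ages, and Sdk1 in each except cluster 18 at 8 weeks.

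The interferon list was lower in AS glomerular endothelial-like cells at 5 weeks, with a median of -0.41 and 3 of 19 members at least 1.5-fold lower, Iigp1 at -0.87 leading, and higher at 8 weeks, with a median of 0.37 and 2 of 16 members higher, Ifit1 at 0.79. The antigen presentation list had medians of -0.63, with 5 of 9 members lower, and 0.09 at percentile 78.2. The unfolded protein response list had a median of -0.01 at 5 weeks and of 0.36 at 8 weeks, above all random lists, with 3 of 14 higher, Hspa5 at 0.82. The immediate-early list had medians of 0.17 at percentile 99.8 and 0.30 above all random lists, with Hsph1 at 0.93 at 8 weeks. The circadian list had medians of -0.35 below all random lists and -0.26 at percentile 0.03, and the glucocorticoid list a median of -0.28 at percentile 0.13 at 8 weeks, with Zbtb16 at -1.98 and Fkbp5 at -1.57. The injury list had medians of 0.10 and 0.35, at percentiles 87.1 and 99.9, with Cd9 at 0.86 at 8 weeks. The basement membrane list had medians of -0.12 and 0.12, at percentiles 0.02 and 93.1, with Col18a1 at -0.85 at 5 weeks and Nid1 at 0.59 at 8 weeks. The oxidative phosphorylation list had medians of 0.22 above all random lists and 0.11 at percentile 95.6. At 8 weeks the interferon median was 0.23 and the immediate-early median 0.13 in cells with a low immediate-early share, and the injury median was 0.09 with no expression floor. With the WT library of the other age the interferon medians turned to 0.22 and -0.34, and at 8 weeks the circadian median to 0.19 and the glucocorticoid median to 0.51. The 5-week medians were -0.03 for antigen presentation, 0.05 for oxidative phosphorylation and -0.91 for circadian clock with that library, and the 8-week injury median 0.57. With it Ifit1 was at -0.19, Hsph1 at 0.39 and Nid1 at 0.06 at 8 weeks. It moved the basement membrane medians to 0.31 and -0.28 and the 5-week immediate-early median to -0.0006.

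The endothelial signalling list had medians of 0.02 and -0.06, at percentiles 47.9 and 8.53, with Ednrb and Thbd (0.79 and 0.71) higher and Angpt1 lower at 8 weeks (-1.14). The 8-week ratio of Thbd fell below 1.5-fold at resolution 2 (0.31) and in cells with a low immediate-early share (0.39), and its 5-week ratio was 0.26 with the WT library of the other age. Medians at 5 and 8 weeks were 0.08 and -0.01 for TNF superfamily genes, -0.11 and 0.06 for NF-kB, -0.04 and 0.05 for TGF-beta and interstitial matrix, 0.14 and 0.04 for p53 targets, -0.01 and 0.13 for actin cytoskeleton, and -0.06 and 0.25 for cholesterol synthesis. With median-of-ratios scaling the 8-week TNF superfamily median turned to 0.03. The slit diaphragm list, whose genes these cells should lack in part, had a median of 0.02 at 5 weeks and of -0.39 at 8 weeks, below all random lists, with 11 of 24 members lower, Magi2 at -2.10 and Ptpro at -1.50. Without genes at a free RNA level the 8-week median was -0.07, and with the WT library of the other age it turned to 0.12, with Magi2 at -0.54 and Ptpro at -0.02. The podocyte markers fixed for naming summed to 1491 CPM in WT and 1632 CPM in AS glomerular endothelial-like cells at 5 weeks and to 2568 and 1623 CPM at 8 weeks.

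Mesangial-like cells had the fewest cells, 161 of them in the WT 8-week library. Cntn5, a neuronal adhesion molecule gene, stood at 180.3 CPM in WT and 373 CPM in AS at 5 weeks and at 149.7 and 546 CPM at 8 weeks, log2 ratios of 1.03 and 1.83. Tmem181b-ps (1.01 and 1.05), Cdk5rap1 (0.93 and 1.36) and Gpm6b (0.64 and 0.87) were also higher at both ages. Lower at both ages were the lysyl oxidase-like gene Loxl2 (-1.04 and -0.81), the matrix gene Frem2 (-0.75 and -0.90), Scd2 (-0.94 and -0.63), Anks1b (-0.57 and -0.86) and Slc27a3 (-0.51 and -0.60). Among the highest at 5 weeks were Atf7ip2 (1.73), Angptl4, an inhibitor of lipoprotein lipase (1.62), Eps8l1 (1.37) and the netrin receptor gene Dcc (1.32). The chemokine Cxcl9 was lowest, at 191 CPM in WT and 2.13 CPM in AS (-4.78, interval -4.92 to -4.63), with Nlrc5 (-1.79), B2m (-1.72), H2-K1 (-1.71) and Tgtp2 (-1.70). At 8 weeks Slc15a2 had 1 UMI in WT and 487 in AS (2.37, interval 1.88 to 2.5, and 4.05 with a pseudocount of 1 CPM), and the matrix glycoprotein gene Tnc had a log2 ratio of 1.27. The lowest at 8 weeks were Kap (-3.78), S100g (-2.64), Klk1 (-2.44), Zfp385b (-2.10) and Gabrb1 (-2.05). With doublets kept Zfp385b and Gabrb1 were at -0.60 and -0.58, and at resolution 0.5 the 8-week ratios of Frem2, Anks1b and Slc27a3 were -0.28, -0.36 and -0.31. Against the WT library of the other age Cxcl9 turned to 0.15 and Slc15a2 to 1.13 at 5 weeks, where Nlrc5 was at -0.05, B2m at -0.25, H2-K1 at -0.81, Tgtp2 at -0.25, Scd2 at -0.21 and Angptl4 at 0.26. At 8 weeks it put Slc15a2 at 0.11, Tnc at 0.29, Zfp385b at -0.32, Gabrb1 at 0.41, Slc27a3 at 0.0141, Anks1b at -0.31, Kap at 0.0067, S100g at 0.0806 and Klk1 at 0.0542. Of 40 named genes and leading list members past 1.5-fold at 5 weeks 25 stayed past it with that library, and of 40 at 8 weeks 12. The named ratios in this class had counting interval arms with a median of 0.176 and a largest of 0.433.

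Among mesangial-like lists, the interferon list had a median of -0.50 at 5 weeks, with 8 of 19 members lower and Ifi27l2a at -1.35, and of 0.61 at 8 weeks, with 9 of 16 higher and Irf7 at 1.03. The antigen presentation list had medians of -1.05, with 7 of 9 lower, and 0.09 at percentile 71.1. The unfolded protein response list had medians of -0.17 at percentile 0.01 and 0.32 above all random lists, with Sdf2l1 at 0.89 and Hspa5 at 0.88 at 8 weeks. The actin cytoskeleton list had medians of -0.28, with 5 of 23 lower and Tpm2 at -0.66, and 0.30, with none past 1.5-fold. The complement list had medians of -0.40 and -0.55 at percentiles 0.03 and 0.02, with none of 5 members past 1.5-fold at 5 weeks and 2 of 6 lower at 8 weeks. Those 2, Cd55 at -1.63 and Cd59a at -0.63, were at a free RNA level, and the 8-week median was -0.15 with no expression floor and -0.25 with doublets kept. The basement membrane list had medians of -0.26 at both ages, below all random lists at 5 weeks and at percentile 0.01 at 8 weeks. Its lowest members at 8 weeks, Col4a5 and Col4a4, are podocyte genes. The slit diaphragm list had medians of -0.26 and -0.88, with Thsd7a at -1.54 and -3.23, and of -0.08 and -0.2039 without genes at a free RNA level. With these left out the 8-week basement membrane median was -0.08. With the WT library of the other age the interferon medians turned to 0.21 and -0.19, and the 5-week antigen presentation median was -0.24, with Ifi27l2a at 0.37 at 5 weeks and Irf7 at -0.14 and Cd59a at 0.27 at 8 weeks. That library also put the slit diaphragm medians at -1.26 and -0.26, the basement membrane medians at -0.15 and -0.52, and at 8 weeks the actin median at 0.12 and the unfolded protein response median at 0.475. The podocyte markers fixed for naming summed to 1229 CPM in WT and 935 CPM in AS mesangial-like cells at 5 weeks, and to 4282 and 1171 CPM at 8 weeks.

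The endothelial signalling list in mesangial-like cells had medians of -0.08 and -0.11 at percentiles 2.81 and 5.20, with Vegfa, a podocyte product, at -0.72 and -2.25. Medians at 5 and 8 weeks were -0.05 and 0.11 for the injury list, with Ccn1 at -1.43 and -0.16, -0.17 and 0.03 for NF-kB, with Cxcl10 at -1.27 and 0.11, 0.12 and 0.04 for p53 targets, 0.14 and 0.13 for the immediate-early list, and 0.14 and 0.11 for oxidative phosphorylation. For TGF-beta and interstitial matrix they were 0.009 and 0.15, and the first was -0.003 with median-of-ratios scaling. The circadian list had medians of -0.04 and -0.19, and the glucocorticoid list of -0.14 and -0.52, with Zbtb16 at -0.10 and -1.44. The 8-week glucocorticoid median turned to 0.26 with the WT library of the other age. Cholesterol synthesis had enough members at 8 weeks only, with a median of 0.15 at percentile 87.2. The TNF superfamily list had fewer than 5 measured members in this class, and the complement list fewer than 5 in the other classes.

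**Figure D4:**
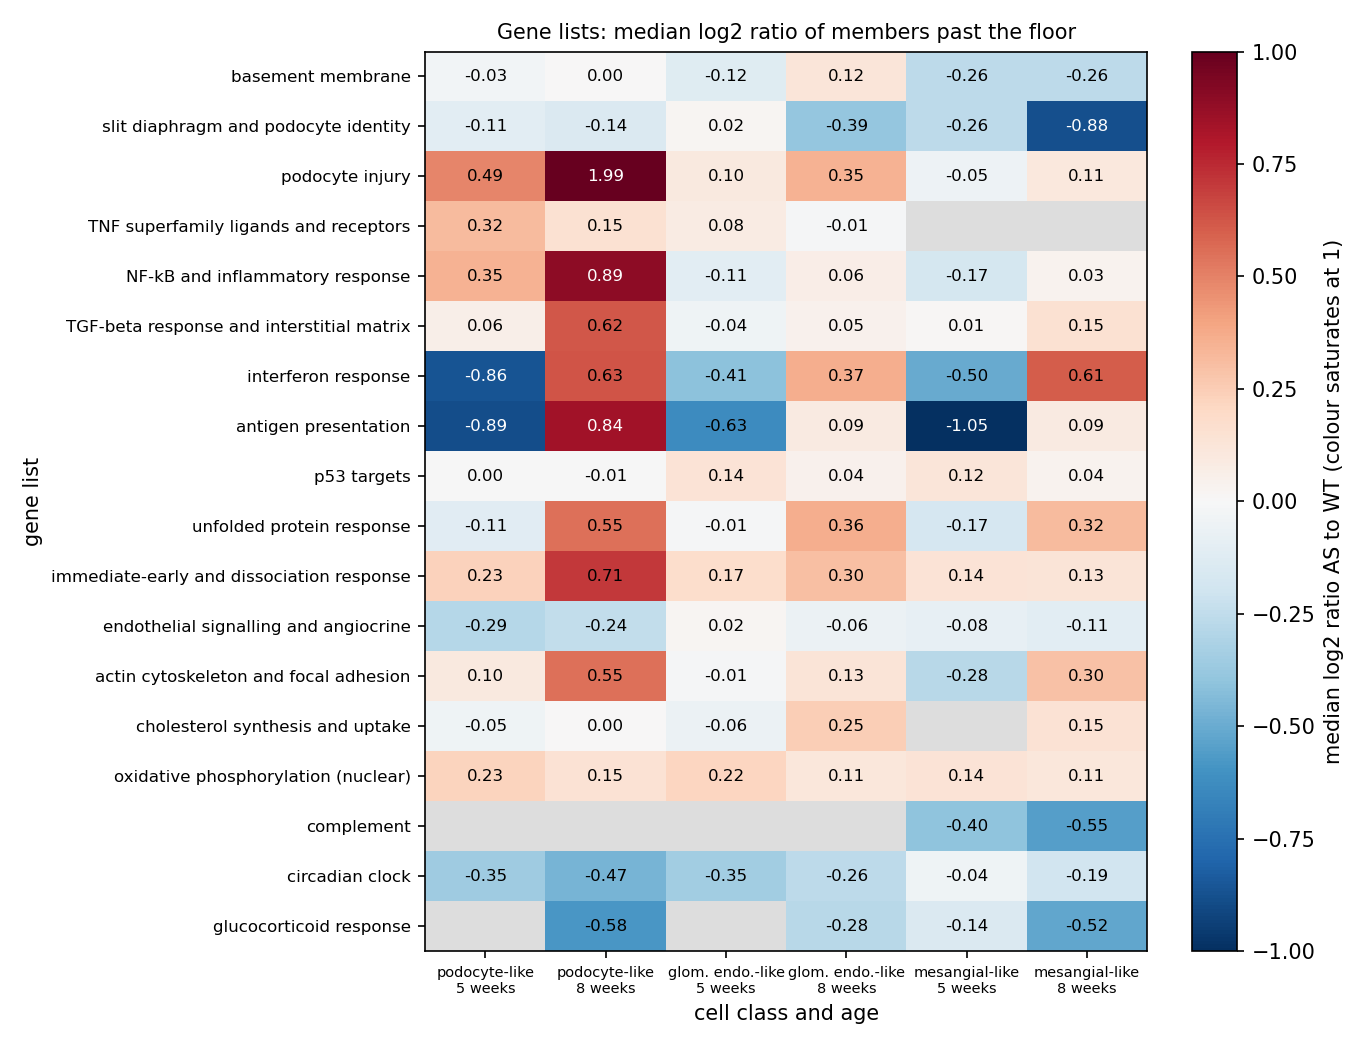
Median log2 ratio of AS to WT of each gene list (vertical) in each cell class and age (horizontal), over the members past the expression floor, with grey where fewer than 5 members were measured. The podocyte injury list reaches 1.99 in podocyte-like cells at 8 weeks, and the interferon list is below 0 at 5 weeks and above 0 at 8 weeks in all 3 classes.

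The libraries were also compared for measures that could move with genotype. Y-linked genes summed to between 283 and 389 CPM in every main class and library, and Xist to 0.472 CPM or less, so all libraries came from male mice by these genes. Proximal tubule markers summed to 92.2 CPM in podocyte-like cells of the WT 8-week library, 185 CPM in glomerular endothelial-like and 103 CPM in mesangial-like cells, against 22.4 CPM or less in every other library. Hemoglobin genes reached 269.99 CPM in AS glomerular endothelial-like cells at 5 weeks and 114 CPM in WT. The immediate-early list made up 1573 CPM of WT and 1866 CPM of AS podocyte-like counts at 8 weeks. Mitochondrial genes made up 2.58% of WT and 2.77% of AS podocyte-like UMIs at 5 weeks and 2.58% and 2.15% at 8 weeks, and ribosomal protein genes 4.18% and 4.31% at 5 weeks and 4.24% and 3.94% at 8 weeks. In glomerular endothelial-like cells the mitochondrial share was 2.69% and 2.72% at 5 weeks and 2.66% and 1.88% at 8 weeks, and the ribosomal protein share 2.78% and 3.26% at 5 weeks and 2.83% and 3.37% at 8 weeks. The immediate-early list made up 1876 and 2223 CPM there at 5 weeks and 2293 and 2841 CPM at 8 weeks. Mesangial-like cells had mitochondrial shares of 2.89% and 2.79% at 5 weeks and 2.74% and 2.18% at 8 weeks, ribosomal protein shares of 2.43% and 2.85% at 5 weeks and 2.86% and 3.07% at 8 weeks, and immediate-early levels of 1077 and 1198 CPM at 5 weeks and 1438 and 1480 CPM at 8 weeks. Age, library and WT animal cannot be separated in this design.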

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

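Of the tests in this part, the one for a few interferon-high cells was chosen before its result was seen, and those for genotype and for the WT 5-week library, like the use of the WT library of the other age, after. Each result here stands out because AS was on opposite sides of WT at 5 and 8 weeks, and the difference was not tested, since each group has 1 library.

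The interferon list in podocyte-like cells was lower in AS at 5 weeks and higher at 8 weeks, and its median log2 ratio was 1.49 larger at 8 than at 5 weeks. In glomerular endothelial-like cells the difference was 0.78 and in mesangial-like cells 1.11. The antigen presentation list in podocyte-like cells differed by 1.73, the gene B2m there by 3.31 and the gene Gbp2 by 2.74. The cluster left unnamed for low purity, interferon-rich and with 151 of its 156 cells from the WT 5-week library, was outside all classes in the main clustering. With doublets kept, a podocyte-like cluster of 106 cells held 102 from the WT 5-week library. At resolution 2 a podocyte-like cluster of 109 cells held 104 from that library. Whether these are the same cells was not tested.

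An effect of genotype that is alike at both ages cannot be told apart from differences between the WT libraries, because the 8-week interferon median in podocyte-like cells was 0.63 with the WT library of its own age and -0.72 with the other. A difference between the WT libraries could give the pattern, as WT at 8 weeks was below WT at 5 weeks in all 3 classes, with a highest median of -0.69. That value holds both WT libraries, so it does not tell whether the 5-week library was high or the 8-week library low. The test for a few interferon-high cells summed UMIs of the interferon and antigen presentation lists together, per thinned podocyte-like cell. At 5 weeks the median cell held 11 of these UMIs in WT and 7 in AS, or 0.636 of WT. A few high cells alone could not give this lower median. The interferon list by itself and the other classes were not tested in this way, so a few interferon-high cells stay open there. An effect of the mutation that differs with age was not tested and stays open.

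The unfolded protein response list in mesangial-like cells differed by 0.48 between the ages. The actin cytoskeleton list in mesangial-like cells differed by 0.58. Slc15a2 differed by 4.04 in glomerular endothelial-like cells, where WT had 583 UMIs at 5 weeks and 2 at 8 weeks. In mesangial-like cells Slc15a2 differed by 3.51, with 295 and 1 UMIs in WT.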

How the results depend on the processing

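The WT library of the other age, clusters of low depth given a name, and the removal of genes at a free RNA level were alternatives chosen after the results were seen, and the other 11 were fixed beforehand. Over 667 results and all alternatives, 7426 values were computed, of which 6031 stayed within the counting spread (for a list, 0.5 of the range of random lists; for a correlation, 0.1), 1322 moved past it with the same sign or without a call, and 73 reversed. A list was called with a percentile in the outer 2.5 on either side and an absolute median of at least 0.2, and a gene at 1.5-fold with an interval that excludes 0. Each group has 1 library. The main ratios set each AS library against the WT library of its own age, and no test across libraries was run.

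Tnfsf15 in podocyte-like cells stayed higher in AS under every alternative. Its log2 ratio was 2.39 at 8 weeks with median-of-ratios scaling, 1.56 at 5 weeks and 2.4 at 8 weeks with a pseudocount of 1 CPM, and 2.18 at 8 weeks with the mean of each cell's CPM. Thinning to 5000 UMIs brought the shares of cells with a Tnfsf15 UMI to 12.9% and 33.3% at 5 weeks and 15.3% and 54.0% at 8 weeks (WT, then AS), because cells hold fewer UMIs by construction. Col4a5 stayed lower, at -0.80 with median-of-ratios scaling and -0.78 with the mean of cell CPM at 8 weeks. In cells with a low immediate-early share it was -1.42 at 5 weeks and -0.72 at 8 weeks. The cause was not tested.

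The podocyte injury list stayed higher at both ages. Its 8-week median in podocyte-like cells was 2.44 with a pseudocount of 1 CPM, 1.66 with the mean of cell CPM, 1.23 in cells with a low immediate-early share, 1.232 with no expression floor and 2.61 without genes at a free RNA level. At 5 weeks it was 0.23 with no floor and 0.76 with doublets kept. The interferon list in podocyte-like cells was -0.51 at 5 weeks and 0.32 at 8 weeks with no floor, where weakly counted genes enter by construction, and -1.32 at 5 weeks at resolution 2. The correlation of the ages in glomerular endothelial-like cells was 0.167 in cells with a low immediate-early share, 0.185 with no floor and 0.2003 at resolution 2. Podocyte-like shares at 8 weeks were 50.5% in WT and 36.6% in AS with a minimum of 1000 genes and 2000 UMIs. At 5 weeks they were 29.1% in WT with doublets kept, and 29.4% in WT and 24.3% in AS at resolution 2. The cause of these moves was not tested.

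Reversals under the alternatives fixed beforehand were few. With doublets kept, podocyte-like cells had Cxcl10 at -0.65 at 5 weeks, the endothelial signalling list at 0.45 at 5 weeks and the glucocorticoid list at 0.16 at 8 weeks, and mesangial-like cells had Kdr at 0.69 at 8 weeks. Cxcl10 was also at -0.22 at resolution 2. In cells with a low immediate-early share the immediate-early list at 5 weeks was at -0.0092 in podocyte-like cells, a selection on the list itself. The cause of the other reversals was not tested.

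With the WT library of the other age, 67 results reversed, 454 moved and 126 stayed. This alternative adds the difference between the WT libraries with opposite signs at the 2 ages by construction. In podocyte-like cells Tnfsf15 was at 1.21 and 2.52, Col4a5 at -0.98 and -1.41 and the injury list at 0.77 at 5 weeks, and the correlation of the ages was 0.438. Reversed in podocyte-like cells were, at 5 weeks, Camk1d 1.83, B2m 0.18, Gbp2 0.63, Igtp 0.0376, Psmb9 0.24 and Tap1 0.14, and, at 8 weeks, B2m -1.35, Tsc22d3 0.21, S100g 0.0257, Gbp2 -0.72, Kap 0.0277, Fkbp5 0.0032 and Psmb9 -0.53. The antigen presentation list there was at 0.18 and -0.21, and the interferon list at -0.72 at 8 weeks. No median against this library is given for the podocyte-like interferon list at 5 weeks or glucocorticoid list at 8 weeks. Their absence here does not show that they held, and members of both lists are among the reversed genes above. Reversed in glomerular endothelial-like cells at 5 weeks were Olfml2b 0.56, Gbp3 0.47, Slc15a2 1.54, Tap1 0.26 and Iigp1 0.091. At 8 weeks Per2 0.42, Olfml2b -0.97, S100g 0.0258, Tnfsf10 -0.43, Gbp3 -0.53, Kap 0.13, Nphs1 0.58, Klk1 0.0574, Ccn2 0.38, Clu 0.23, Fxyd2 0.10, Zbtb16 0.51, Plk2 -0.0366, Slc15a2 -0.11, Fkbp5 0.37, Acta2 0.31, Ifit1 -0.19 and Plce1 0.15 reversed there. List medians that reversed in this class were interferon at 0.22 and -0.34, and at 8 weeks slit diaphragm at 0.12, circadian clock at 0.19 and glucocorticoid at 0.51, and the correlation of the ages was -0.259. In mesangial-like cells, Cxcl9 0.15, Mt1 -0.21, Igtp 0.16, Ifi27l2a 0.37, Slc15a2 1.13 and Iigp1 0.10 reversed at 5 weeks. At 8 weeks Cd55 0.0068, Cd59a 0.27, S100g 0.0806, Slc27a3 0.0141, Errfi1 0.0267, Gabrb1 0.41, Kap 0.0067, Klk1 0.0542, Irf7 -0.14, Plat 0.0245, Zbtb16 0.61 and Ifi27l2a -0.73 reversed there. The interferon list was at 0.21 and -0.19, the glucocorticoid list at 0.26 at 8 weeks and the correlation of the ages at -0.263.

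Other results that moved without a reversal numbered 209 in cells with a low immediate-early share, 161 with the mean of cell CPM, 148 with a pseudocount of 1 CPM, 85 at resolution 2, 75 with median-of-ratios scaling, 69 with doublets kept and 62 at resolution 0.5. They numbered 17 with low-depth clusters named, 17 with no floor, 11 with the stricter minimum, 6 without genes at a free RNA level and 4 with a mitochondrial maximum of 10%, and these counts include the values above. Depth limited mesangial-like cells most, with 161 cells and 2116878 UMIs in the WT 8-week library.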

Other observations

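Of the tests in this part, those on deeper AS libraries, dissociation stress, podocyte doublets, free RNA over all slit diaphragm genes and a shifted subset were written before their results were seen. The tests on Tnfsf15 in other cell types, on tubule genes, on tubule and podocyte markers and on the podocyte genes nearly absent from AS mesangial-like cells were written after.

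Outside the 3 main classes, Tnfsf15 was at 45.5 CPM (20.8 to 86.4) in the distal tubule-like cells of the AS 8-week library, from 9 UMIs, and at 17.9 CPM in those of the WT 8-week library, from 21 UMIs.

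Higher Tnfsf15 in AS podocyte-like cells could come from deeper AS libraries, from RNA of other cells, or from stress during dissociation. Deeper libraries alone could not give it, because after thinning the 8-week share of cells with a Tnfsf15 UMI was 3.54 times as high in AS as in WT. RNA of the other main classes could not, because their highest level in AS at 8 weeks was 1.59% of the podocyte-like level. Dissociation stress as measured by the immediate-early list could not give all of it, because in cells with a low immediate-early share the 8-week log2 ratio was 2.23. The biological explanation, an effect of the mutation, stays open with 1 library per group.

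Podocyte and tubule genes were lower in AS than in WT mesangial-like and glomerular endothelial-like cells at 8 weeks, which could reflect RNA from other cells in the WT 8-week library. A cluster left unnamed for low depth held 771 cells, 763 of them from that library, with a median of 1232 UMIs. Its leading genes included the tubule genes Kap, S100g, Fxyd2 and Klk1. They also included Opcml, Lingo2 and Astn2, leading genes of podocyte-like cluster 2. Whether these barcodes hold free RNA was not tested. For podocyte doublets the test could not tell, as 9 of 161 cells held 44.6% of the slit diaphragm UMIs. The test of free RNA written beforehand came out against it for podocyte genes, with a rho of -0.0864 over 22 slit diaphragm genes between mesangial-like and podocyte-like levels, a list not limited to genes that mesangial-like cells lack. A rho of 0.916 over the 12 of these nearly absent from AS mesangial-like cells, and a highest class mean of Kap, S100g and Klk1 UMIs per cell 1.08 times the lowest, decide nothing, because these genes were chosen for the pattern. For tubule genes, markers fixed before the data were seen, without Kap, had a highest class mean of UMIs per cell 1.72 times the lowest, as an even spread of free RNA in that library needs. Podocyte markers had a mean of 56.3 UMIs per mesangial-like and 16.02 per glomerular endothelial-like cell, a ratio of 3.51, which lies between the bounds for either answer. No biological explanation was tested.

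A hypothesis of this re-analysis was that the 5-week AS podocyte-like cells hold a subset already shifted towards the 8-week response, with the rest like WT. The lower quartile of the sum over the 50 genes highest at 8 weeks was 3.67 times as high in AS as in WT at 5 weeks, and the 90th percentile 3.0 times, so the data spoke against a subset alone and the whole distribution lay higher. The genes were chosen at 8 weeks, and the libraries compared were not used to choose them.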
